A study of Drosophila melanogaster with 5 samples.

How the data were processed

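Total RNA of whole Drosophila melanogaster larvae of the third instar was labelled with Cy3 and hybridised to NimbleGen expression arrays, per the labels' protocols. Each array carried a single sample, so no dye orientation entered the comparison. The 5 arrays analysed here comprised 2 wild-type arrays (w1118), which carry the replicate numbers 1 and 3, and 3 arrays of dDPa3/dDPa4 transheterozygous larvae, numbered 1 to 3. The series' design text speaks of more replicates for the wild type than these, and a wild-type array numbered 2 was not analysed here. The genotype field of the labels was followed; the sample titles call the same samples a knockdown. No label says whether replicates came from separate cultures or collections of larvae, so p-values measure only the spread between these samples, which may be technical.

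The deposited table holds 1 value per transcript and array, for 16637 FlyBase transcript identifiers. The authors summarised probes with RMA in the R package oligo, per the submitters' processing notes, which give no versions. The deposited values were taken to be log2 RMA values: RMA writes log2, and all values lay below the 16 that a 16-bit scanner allows on that scale. The base itself is stated nowhere in the sources used here, and with another base the fold changes would differ while the tests would not. RMA corrects background, equalises the distributions of the arrays and summarises probes. The deposited columns accordingly had nearly equal medians, so a shift shared by most transcripts would not be visible in them. The genome build, the annotation release and any detection filter are not given in the sources used here.

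Gene names were taken from the RefSeq gene table of Drosophila melanogaster Release 6 plus ISO1 MT, whose synonyms contain some FlyBase transcript identifiers. This named 44 of the 16637 transcripts, 16 with 1 gene and 28 with several. Transcripts with several genes carry a main and an upstream reading frame by those synonyms, and their value cannot be divided between the genes. The array's annotation release is unknown, so no coordinates are given. Before the data were examined, 28 gene lists with 784 genes in the table were fixed (DNA replication, G2 and mitosis, the dREAM and E2F complex, DNA repair, apoptosis, germline, sex, metabolism, mitochondria, muscle, ecdysone, cuticle, gut, immunity, stress, growth and cell type markers). None of the 784 genes was among the named transcripts, where 80% of a list was required, so the list tests were void and are not reported. Dp was likewise not analysed here.

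The main test was limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the deposited values, with genotype as the only term, all 5 arrays in 1 fit, and Benjamini-Hochberg adjustment over all 16637 transcripts at a threshold of 0.05. Transcripts rather than genes were tested because too few were named. No transcript was filtered out of the main fit. Pseudocounts and depth play no part in these values. The fit had 3 residual degrees of freedom per transcript, to which moderation added 2.32, and the number of arrays limits the precision. The design, the gene lists and the rule for named genes were fixed before the data were examined. That rule takes Dp, up to 12 changed transcripts at each end of the range of log2 differences with all arrays of the genotypes apart, and members of the gene lists. None of the 24 transcripts it selected had a gene name, so 2 of each direction are given by identifier. Gene names that appear in the results were therefore chosen outside the rule, after their values were seen, as was the transcript with the largest difference, which did not pass the test.

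The fit was tested on simulated data with the transcript means and the variance distribution of these arrays and 200 changed transcripts, over 20 simulations. It called 0.9% of the changes simulated at 1 on the log2 scale, 46.7% of those at 2 and 87.7% of those at 4, with on average 4 false calls among 71.7. The simulated noise was independent between transcripts and had the same variance in both genotypes. On the arrays transcripts varied together, so the share of false calls may not carry over. The adjustment is stricter where fewer transcripts pass, and 271 passed on the arrays. The shares called in the simulations may therefore be too low for these arrays. Alternatives were 3 other normalisations (median centring, repeated quantile normalisation, cyclic loess), eBayes with trend and robust settings, no moderation, array weights, filters that removed the 25% or the 50% of transcripts with the lowest mean, the replicate number as a block, other thresholds, and each array left out in turn. The wild-type and mutant arrays share the replicate numbers 1 and 3. No label gives these numbers a meaning across genotypes, so the main fit has no block. Figures were drawn with matplotlib 3.10.9.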

Results

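The arrays compared transcript levels in whole larvae carrying mutant alleles of dDP with those in w1118 wild-type larvae. DP is the dimerisation partner with which E2F transcription factors bind DNA, and the mutant larvae carried the dDPa3 and dDPa4 alleles in trans. There were 3 mutant and 2 wild-type arrays, each giving an RMA value, taken to be log2, for 16637 transcripts. The level of dDP itself was not analysed here. Array medians lay between 11.64 and 11.69, with values from 4.98 to 15.73. The wild-type arrays correlated at r = 0.986 across transcripts, the mutant arrays at 0.957 to 0.972, and arrays of different genotype at 0.927 to 0.965. The first principal component held 57.2% of the variance and separated the genotypes. On it, mutant replicate 2 lay nearest to the wild type, at 15.6, against 43.8 and 48.3 for mutant replicates 1 and 3 and -45 and -62.7 for wild-type replicates 1 and 3.

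In dDP mutant larvae 236 transcripts rose and 35 fell relative to the wild type, which together are 1.63% of those measured (limma with genotype as the only term, Benjamini-Hochberg adjusted p below 0.05; 3 mutant and 2 wild-type arrays). The rises that passed were large. Their median was 2.21 on the log2 scale, 140 of the 236 were at least 2 and 18 were at least 4. The smallest rise that passed was 1.1. The fit called 0.9% of changes simulated at 1, but in simulations with fewer calls and so a stricter adjustment. The falls had a median of -1.8, and 14 of the 35 were at least 2 in size and 0 were at least 4. For all 271 transcripts every mutant array lay beyond both wild-type arrays in the direction of the change. Without regard to the test, 970 transcripts were higher and 1222 lower in the mutant by at least 1 on the log2 scale. The excess of rises was thus not found among all differences of that size, but of those of at least 2, 75.2% were higher. With the replicate number as a block, which left 1 residual degree of freedom, falls outnumbered rises among the calls. Over all 16637 transcripts 3007 had an unadjusted p below 0.05, of which 1666 were higher and 1341 lower in the mutant, where 832 would be expected with no difference between arrays other than independent noise. The genotypes did not overlap for 21.6% of transcripts in the higher direction and for 18.1% in the lower. Chance gives 10% in each on average over the splits of the arrays. Transcripts varied together, so a single split can lie far from that.

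The number of transcripts past the threshold rested on having all 5 arrays. Without wild-type replicate 1, wild-type replicate 3, mutant replicate 2 or mutant replicate 3, limma called 0 transcripts at the same threshold, with 2092, 1219, 2931 and 2601 at an unadjusted p below 0.05. Without mutant replicate 1 it called 118. With all arrays but no moderation of the variance limma called 0, with 2035 at an unadjusted p below 0.05. Each of the 271 kept its direction in all of these fits, which was fixed in advance because the genotypes did not overlap for any of them. In the fits that kept both wild-type arrays each also had an unadjusted limma p below 0.05. The 271 were chosen for small p-values on the same arrays, so this is no separate support.

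**Figure D1:**
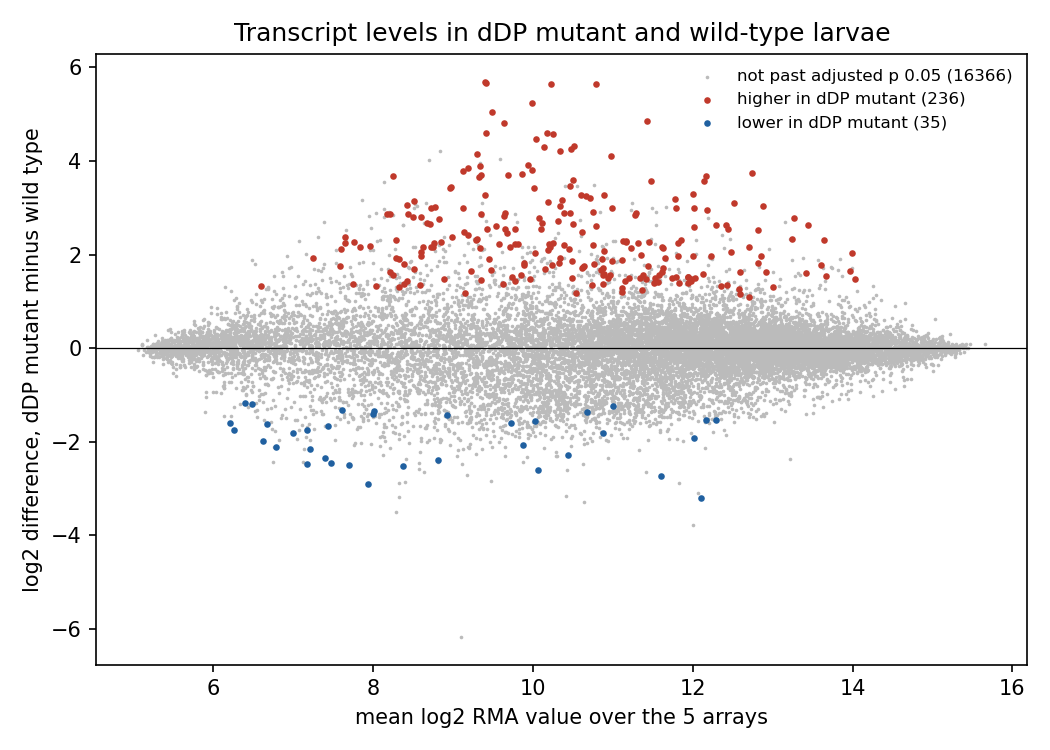
Log2 difference between dDP mutant and wild-type larvae (y axis) against the mean log2 RMA value over the 5 arrays (x axis), 1 point per transcript. The 236 transcripts higher in the mutant (red) reach a difference of 5.69, the 35 lower ones (blue) reach -3.21, and most of both lie below the median signal. The lowest grey point, at -6.17, did not pass the test.

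The transcripts that rose mostly had low array signals in wild-type larvae. Signals of different transcripts also depend on their probes, so these ranks describe signal and not abundance. The median transcript of the 236 stood at the percentile 20.9 of wild-type signals and at the percentile 48.3 of mutant signals, which is a move from 8.88 to 11.53 on the log2 scale. On both wild-type arrays 137 of the 236 lay below the lower quartile of signals, and 10 of these exceeded the array median on all 3 mutant arrays. The median of the 35 that fell stood at the percentile 22.9 in the wild type and 11.7 in the mutant, with 24 of the 35 below the lower quartile on all 3 mutant arrays. In 4 groups of equal size by mean signal, from the dimmest to the brightest, 69, 114, 42 and 11 transcripts rose and 22, 9, 4 and 0 fell. The median standard error in these groups was 0.28, 0.31, 0.23 and 0.19.

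The largest differences among the rises belonged to transcripts close to the bottom of the scale in the wild type. FBtr0080106 had a mean of 5.99 ± 0.254 (SD, n = 2) in the wild type and 11.7 ± 0.719 (SD, n = 3) in the mutant, a difference of 5.69 with a standard error of 0.441 (limma adjusted p = 0.016). FBtr0077271 went from 6.02 ± 0.053 to 11.7 ± 0.664, a difference of 5.66 with a standard error of 0.401 (limma adjusted p = 0.0154). Among the falls, FBtr0080564 had a mean of 14.0 ± 0.117 in the wild type and 10.8 ± 0.547 in the mutant, a difference of -3.21 with a standard error of 0.344 (limma adjusted p = 0.0276). FBtr0076232 fell from 9.68 ± 0.57 to 6.78 ± 0.251, a difference of -2.9 with a standard error of 0.305 (limma adjusted p = 0.026). These 4 transcripts are given by identifier because none had a gene name in the table used. The largest difference of all was in a transcript that did not pass the test, which is described here after its values were seen. Its mean was 12.8 ± 0.371 (SD, n = 2) in the wild type and 6.63 ± 1.6 (SD, n = 3) in the mutant, a difference of -6.17 with a standard error of 0.918 (limma adjusted p = 0.0508). The mutant values were 8.46, 5.88 and 5.54, all below both wild-type values. Whether the signals near the bottom of the scale, in either genotype, lay above background was not tested here, so the sizes and the order of these differences describe the deposited values only.

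Among the 44 transcripts with a gene name, 0 passed the test, both over all transcripts and adjusted over the list alone (limma). At an unadjusted p below 0.05 there were 7, or 15.9%, all higher in the mutant, against 18.1% of all transcripts. For each of the 7, the 3 mutant arrays lay above both wild-type arrays. The same held for 16 of the 44 in all, and for 4 the mutant arrays lay below both. The 7 had small p-values on the same arrays, so this is no separate support. The largest difference of the 7 was for the transcript shared by Rad1, a subunit of the checkpoint clamp loaded at damaged DNA, and Sws1. Its mean was 11.6 ± 0.007 (SD, n = 2) in the wild type and 12.7 ± 0.22 (SD, n = 3) in the mutant, a difference of 1.18 (95% interval 0.69 to 1.67; limma adjusted p = 0.0639, and 0.0613 adjusted over the list alone). The transcript of SuUR, a chromatin protein that restrains replication of heterochromatin in polyploid larval tissues, differed by 0.61 (0.18 to 1.04; limma adjusted p = 0.171). The transcript of Tgs1, which makes the trimethylguanosine cap of small RNAs, and of moi, a telomere-capping protein, differed by 0.49 (0.09 to 0.89; limma adjusted p = 0.208). NaPi-III, a phosphate transporter, differed by 0.85 (0.43 to 1.27; limma adjusted p = 0.0944). The transcript of CG7950 and Rpp14a, a subunit of ribonuclease P, differed by 0.75 (0.34 to 1.15; limma adjusted p = 0.111). The transcript of Tcs6 and of PIG-P, which acts in glycolipid anchor synthesis, differed by 0.97 (0.18 to 1.76; limma adjusted p = 0.212). The transcript of CG5116 and CG42488 differed by 0.5 (0.05 to 0.95; limma adjusted p = 0.242).

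The values of these genes, like those that follow, were picked out after they were seen. For most of the other named transcripts the interval bounds the difference. In 38 of the 44 the estimate was below 0.5 in size, and in 34 the 95% interval lay within 1 on either side of 0, against 53.3% of all transcripts. The named transcripts had higher signals than most, with a median at the percentile 77.2 of mean signal. The transcript shared by ND-MNLL, a subunit of respiratory complex I, and CG45089 differed by -0.02 (95% interval -0.51 to 0.46), and that shared by Tim10, a chaperone of protein import, and CG42497 by -0.03 (-0.53 to 0.47). Among chromatin genes, the histone gene His4r differed by -0.1 (-0.64 to 0.43), the deacetylase HDAC3 by 0.27 (-0.23 to 0.77) and the remodeller kis by -0.2 (-0.73 to 0.34). Fatp1, which encodes a fatty acid transport protein, differed by 0 (-0.7 to 0.7). The transcript shared by Mvk, the mevalonate kinase gene, and CG33672 differed by -0.04 (-0.46 to 0.38). Uba1, which encodes the ubiquitin-activating enzyme, differed by 0.08 (-0.33 to 0.49). The genes mio and Wdr24, which belong to a complex of the nutrient-sensing TOR pathway, differed by 0.19 (-0.48 to 0.85) and 0.21 (-0.49 to 0.92). The structural genes LanA, encoding a laminin, and alpha-Spec, encoding a spectrin, differed by 0.24 (-0.21 to 0.68) and -0.18 (-0.82 to 0.46). The widest intervals were those of CG31178, at -1.16 (-2.51 to 0.2), and rdx, a substrate adaptor in Hedgehog signalling, at -0.49 (-1.81 to 0.83). The mutant arrays of these transcripts had SDs of 0.883 and 0.889.

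**Figure D2:**
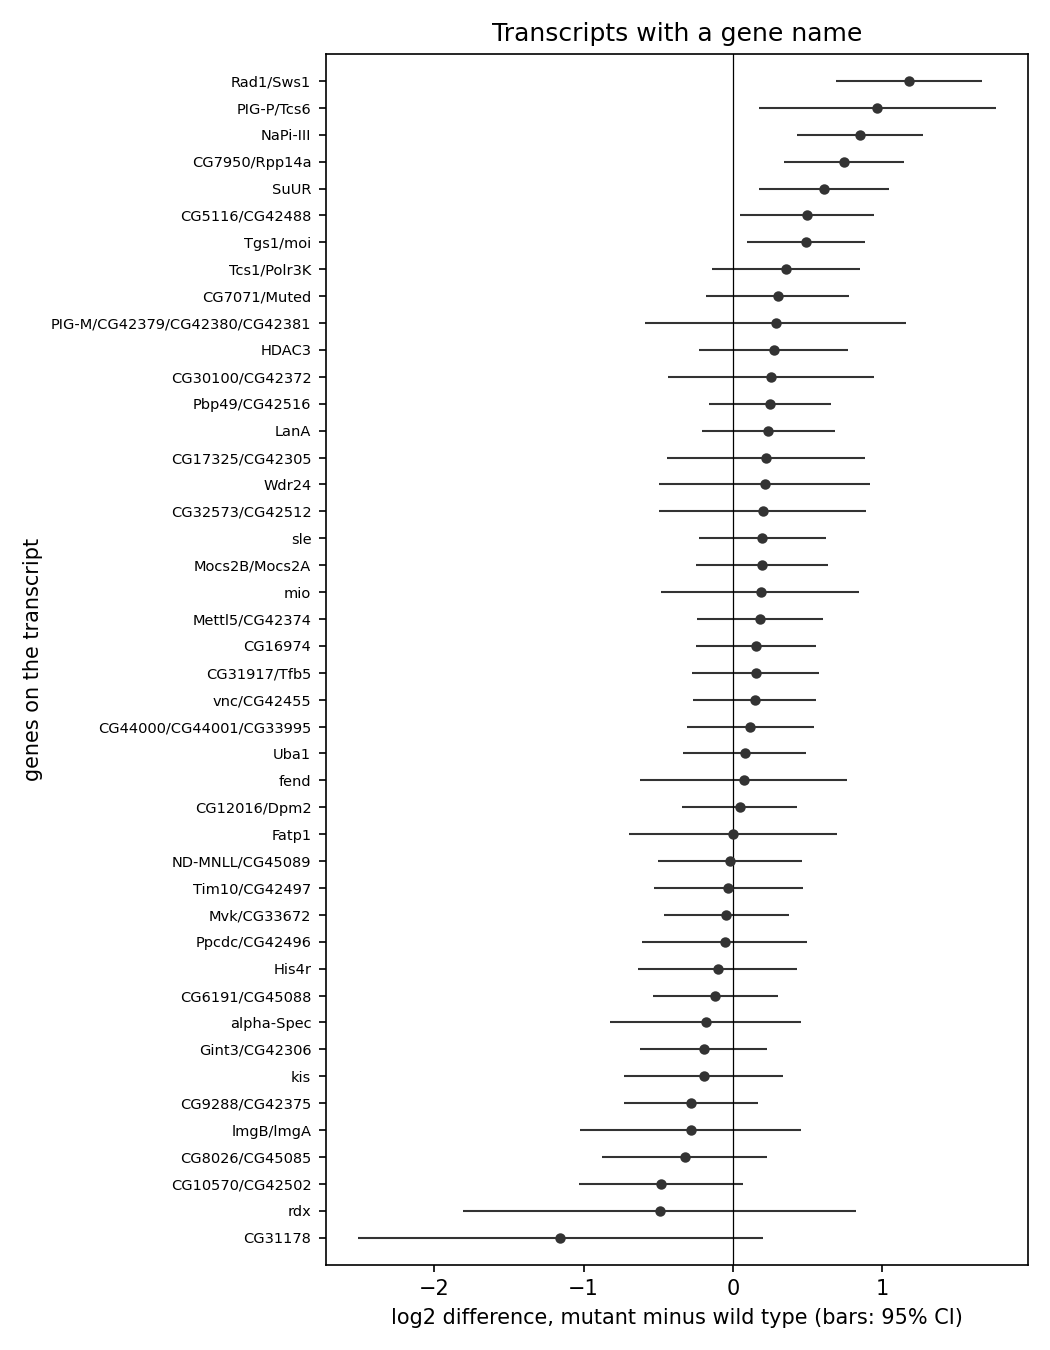
Log2 difference between dDP mutant (3 arrays) and wild-type (2 arrays) larvae with its 95% confidence interval from limma (x axis), for the 44 transcripts with a gene name (y axis; genes sharing a transcript are joined by a slash). The intervals of 7 transcripts lie wholly above 0, from 1.18 for Rad1/Sws1 to 0.49 for Tgs1/moi, and none lies wholly below 0.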

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

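The test without a statistical threshold and the fits at 0.1 with an array left out were chosen after seeing the data. The 271 calls (236 higher, 35 lower) stayed within 1.5 times under median centring, repeated quantile normalisation, cyclic loess, trend and robust settings, and a log2 threshold of 1, between 225 and 287, and no normalisation moved the median of all transcripts beyond -0.026. Without moderation limma called 0, with 2035 transcripts at an unadjusted p below 0.05. Array weights gave 683 (558 higher, 125 lower), and a threshold of 0.1 gave 617 (498 and 119). Removing the dimmest 25% gave 14 lower calls, and removing the dimmest 50% gave 53 calls (49 and 4), where 57 of the 271 remained to be tested. Requiring the genotypes not to overlap and a log2 difference of at least 1, with no test, gave 2074 transcripts (924 and 1150). Leaving out an array gave 0 to 118 calls (0 to 102 higher, 0 to 16 lower) at 0.05 and 0 to 429 at 0.1 (0 to 345 higher, 0 to 149 lower). It was 0 at 0.1 only without wild-type replicate 1 or 3, which leaves a single wild-type array whose spread is assumed to equal that of the mutant arrays. In simulations of those designs 43.7% of changes of 4 on the log2 scale were still called, but 0.1 and 0% of changes of 2. With the replicate block the count was 858, of which 331 were higher and 527 lower (38.6% higher), so the balance between rises and falls turned round, on 1 residual degree of freedom. Same-numbered arrays, which share only a number, deviated together at r = 0.52 and 0.21. Among pairs across genotypes with different numbers, wild-type replicate 3 and mutant replicate 2 did so at 0.4, and the rest were negative. Deviations from genotype means are tied, so the values decide nothing. The cause of these differences was not tested. The differences of the 4 transcripts given by identifier and the 7 named transcripts kept their sign in all 147 refits. The 4 lost their call in 21 refits, and Rad1/Sws1, NaPi-III and CG7950/Rpp14a passed only with array weights, at adjusted p of 0.0181, 0.0353 and 0.0481, the lowest of ranges that reached 0.436, 0.601 and 0.652. Of the 44 named transcripts, 3 passed over the list alone with array weights, 2 with trend and robust settings or without the dimmest 50%, and 1 without the dimmest 25% or mutant replicate 1. Alternatives for Dp, for the gene lists with an estimated correlation and for several features per gene were not run for want of gene names. Depth is not defined for these values, and without background signals no floor can be set.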

Other observations

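The tests of the spread of lower transcripts, at both sizes, the test of signal compression with the genotypes weighted equally, the test of developmental age and the count over other splits of the arrays were chosen after their results or parts of them had been seen, and all patterns were noticed in these data.

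The transcripts that were lower in the mutant also differed between the wild-type arrays. Of the 1222 transcripts with a mutant mean lower by at least 1 on the log2 scale, 87.6% had a higher value in wild-type replicate 3 than in replicate 1, with a median difference of -0.61 (replicate 1 minus 3). Of the 970 higher by at least 1, 43.2% did, with a median of 0.08, and over all transcripts the share was 47.1%. In the mutant the same 1222 transcripts had a median difference of -0.51 between replicates 1 and 3, against -0.16 for the 970. The genotype difference includes both wild-type arrays, so an array with more noise would also tie the sets to it, and this was not tested.

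With genotype as the only term, more transcripts passed the test as higher (236) than as lower (35), although 970 were higher and 1222 lower by at least 1 on the log2 scale. The balance turned round with the replicate number as a block, where falls outnumbered rises among the calls, on 1 residual degree of freedom. The excess was not confined to transcripts with the dimmest or brightest mean signal. Between the quartiles of mean signal 92.3% of calls were higher, and 91.7% with the genotypes weighted equally in that mean. Compression at the ends of the scale stays open even so. A transcript with a mean between the quartiles can lie near an end in 1 genotype, and no floor could be set. Normalisation stays open too: 3 others left at least 86.2% higher but were run on values that RMA had equalised, which they cannot undo. The residual SD of the lower transcripts was 1.53 times that of the higher ones (0.606 against 0.397), with a 95% bootstrap interval over transcripts of 1.43 to 1.59. The interval treats transcripts as independent, which they are not. A larger spread gives fewer calls whether or not the falls are real, since noise also carries more transcripts past 1. These values therefore cannot tell a test that lacked power for falls from a lack of falls. Among differences of at least 2 the lower ones also varied more (residual SD 0.791 against 0.463; 17.9% against 59.3% called), but 236 transcripts were higher and 78 lower before any test, or 75.2% higher, which spread alone does not account for. The real split gave 271 calls and the highest of the other splits 0 (3007 and 1934 at an unadjusted p below 0.05), with 1 of 10 splits as large, and 10 splits are too few for a share under 0.05; an effect of the genotype on the direction stays open.

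Arrays varied along an axis that both genotypes shared. Across transcripts, the difference between replicates 1 and 3 in the wild type correlated with that in the mutant at r = 0.4, and with mutant replicate 1 minus 2 at 0.56, but at -0.07 with mutant replicate 2 minus 3. Transcripts are not independent replicates, so these values describe these 5 arrays. An intensity-dependent hybridisation bias is argued against only as a trend left in these values. The correlation was still 0.4 after a trend on mean signal was removed from each difference. RMA had already equalised the arrays, so a bias of another form stays open. A difference in developmental age between the larvae, which may accompany the mutant genotype, cannot be told apart from handling of the samples, because 0 members of the stage lists had a named transcript.

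Of the 271 changed transcripts, 36 had a neighbour in identifier number that changed in the same direction. They formed 21 pairs, all higher in the mutant, against a median of 2 and at most 10 in 10000 random sets of the same size, and the longest run held 6. Identical probe sets are argued against, since 4.8% of the pairs agreed within 0.1 on all 5 arrays, but partly shared probes stay open: the limit set in advance did not allow for them, and the median difference in level within a pair was 0.4. A relation to the genotype stays open too, since random sets ignore that consecutive identifiers varied together within genotypes, at r = 0.15 between the wild-type arrays and 0.22 between mutant replicates 1 and 3 against 0.2 for the genotype difference. Whether the paired transcripts belong to the same gene or to neighbouring genes was not tested.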
